A study of Homo sapiens with 16 samples.

How the data were processed

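The series holds 16 CLIP-seq libraries, in which RNA bound to a protein was recovered by UV-C cross-linking and immunoprecipitation and then sequenced. The libraries came from HepG2, a liver carcinoma cell line, and from THLE-2, an immortalised line of liver epithelial cells. In each cell line EZH2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), and JARID2, an accessory subunit of the same complex, were precipitated in 2 replicates, described by the labels as biological. Each of these 8 libraries had a matching IgG control library, which makes 8 IgG libraries. A peak list was deposited for each of the 8 libraries of EZH2 or JARID2. Values of the IgG libraries were not analysed here, so their background does not stand beside the peaks.

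Per the submitters' processing notes, reads were aligned to GRCh38 with TopHat2, whose version was not stated. The peak caller, its threshold, the way the IgG libraries entered the calls, the treatment of duplicate reads and the annotation release were not given in the sources used here. Per the file headers, the deposited lists give the tags of each peak, and these values are whole counts of reads of at least 3 per peak, with no normalisation. The deposited lists also give, per the file headers, the maximal height of each peak, a signal in overlapping tags at the summit that was checked never to exceed the tags. The length of each peak in bases, its strand, the gene it was assigned to by the authors and the region class of the assignment complete the lists. Only called peaks were listed, so the total depth of the libraries is unknown. The tags inside peaks ranged from 13267 to 88573 per library, and no model of counts across libraries was fitted, because a gene without a listed peak has no count. Intervals of shares within 1 library are 95% Wilson intervals, which cover counting error only, since tags without molecular identifiers are not independent molecules.

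The 8 lists held 41024 peaks. Gene identifiers were matched without their version to GENCODE release 29; 10523 of 10593 identifiers (99.3%) were found, and 99.4% of the peaks with a matched identifier overlapped that gene. Between 16 and 30 peaks per library carried an identifier that was not found. A gene was called bound in a library when at least 1 peak of any class other than antisense was assigned to it. Under this definition 8678 genes were bound in at least 1 library, and these form the background of the overlap tests. The 7 region classes were coding exon, 3′ UTR, 5′ UTR, noncoding exon, intron, antisense and intergenic, taken from the deposited lists. The 7 RNA classes were taken from the gene biotypes of GENCODE. A few genes were counted but are not reported here singly.

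The comparisons, tests, gene lists and alternatives were fixed before the data were examined, except for those named below as added later. With 2 libraries on each side an exact test cannot give p below 0.333, so genes were classed by presence: bound in both replicates of 1 side and in neither of the other, or bound in both replicates of both sides. The 4 main comparisons set HepG2 against THLE-2 for EZH2 and for JARID2, and EZH2 against JARID2 in HepG2 and in THLE-2. The overlap of each pair of sets was tested with the two-sided Fisher's exact test. Measures with 1 value per library were compared between 4 and 4 libraries by two-sided exact permutation over the 70 splits, where the smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over the classes of a family. The splits were not restricted within a cell line or protein. They treat the 8 libraries as exchangeable, although replicates resembled each other more than other pairs did, so these p may be too small. The interaction of protein and cell line was not tested, and no linear model was fitted. Replicate pairs were ranked among the 105 ways to pair 8 libraries, and groupings by cell line or protein among the 35 ways to divide them into 4 and 4. The Jaccard index of 2 libraries is the number of genes bound in both divided by the number bound in either. Peaks overlapped when they shared at least 1 base on the same strand.

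The genes named in the text were chosen by a rule, and some that it chose are not reported here. For each class of each comparison these were the 10 genes with an official symbol and the largest minimum, over the libraries that bind them, of the tags in their strongest peak. Up to 4 members per gene list were added by the same strength, with EZH2, JARID2 and SUZ12 as components of the complex. Tags given for a gene are summed over its peaks in a library. The 22 gene lists were PRC2 subunits, PRC1 subunits, long noncoding RNAs (lncRNAs) discussed as PRC2 partners, small nuclear and other short structured RNAs, snoRNA host genes, hepatocyte secreted proteins, hepatocyte transcription factors, lipid and cholesterol metabolism, genes recurrently altered in hepatocellular carcinoma, the Wnt, TGF-beta and PI3K, AKT and mTOR pathways, cell cycle and DNA replication, mesenchymal and extracellular matrix genes, epithelial junction and keratin genes, splicing factors, chromatin remodellers and histone methyltransferases, cytosolic ribosomal proteins, histone genes, mitochondrially encoded transcripts, developmental transcription factors, and markers of stellate, fibroblast, endothelial and blood cells. Of 700 list entries 1, CCAT1, was not found in the annotation, so any peaks it had were not counted among the lncRNAs discussed as PRC2 partners. Each list was tested by the two-sided Fisher's exact test of membership against the 2 exclusive classes of a comparison, adjusted over the 22 lists. A test of list members among genes bound on both sides, against all 8678 genes, was chosen after seeing the data.

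Sequence was compared on exonic peaks in GENCODE transcripts, because no genome sequence was at hand. The G percent, the GC percent and the percent of peaks with a run of 3 or more G were set against flanks of equal length 200 nt away in the same transcript, and the difference was tested by exact sign flips over 8 libraries (256 flips, two-sided, smallest p 0.00781). The planned run on intronic peaks was not possible. To see which peaks lie on small nucleolar RNAs (snoRNAs) or small Cajal body RNAs, the peaks were overlapped with 992 such genes of GENCODE on the same strand, and with 1199 of RefSeq, whose table gave no strand. The RefSeq genes were added after the result with GENCODE alone had been seen, and both values are given.

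The alternatives fixed beforehand were the peaks above the median rank of each list by strength, lists cut to the 2264 strongest peaks (the length of the shortest list), genes assigned by peak midpoint, at least 2 peaks per gene, bound in at least 1 replicate, flanks 500 nt away, other measures of overlap and strength, replicate blocks and leaving out each replicate in turn. For both cuts peaks were ranked by tags, then height, then genomic position, so that ties were broken by position. In HepG2 JARID2 replicate 2 and THLE-2 JARID2 replicate 1 the median was 3 tags, also the minimum. The peaks called above the median there include peaks of 3 tags. Alternatives chosen after seeing the data were antisense peaks counted for their listed gene, lists without peaks over snoRNAs, lists without mitochondrial peaks, regions among peaks found in both replicates or with 10 or more tags, and the test of genes bound on both sides with and without snoRNA peaks. The methods were tested on simulated data. All 200 planted separating genes and all 100 planted genes per direction were found, and 13 of 500 null runs of the permutation test passed the threshold of 0.05. These null runs drew 8 independent values, so they do not show how replicates nested in groups affect the test. A planted list of 30 genes was found in 6 of the 8 exclusive classes. It was missed in the largest classes, at adjusted p = 0.171 for EZH2 only in THLE-2 and adjusted p = 0.133 for THLE-2 only with EZH2 (Fisher's exact tests), so a list held mostly by the larger class could not have been seen at that size. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.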

Results

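RNA bound by EZH2 and by JARID2 was mapped by CLIP-seq in HepG2 and THLE-2 cells, with 2 replicates for each protein in each cell line and 1 peak list per library. HepG2 is a line from a liver carcinoma and THLE-2 an immortalised line of liver epithelial cells. EZH2 is the histone H3 lysine 27 methyltransferase of PRC2 and JARID2 is an accessory subunit that takes part in recruiting the complex. The EZH2 lists held 4720 and 4145 peaks in HepG2 and 9122 and 8183 in THLE-2. The JARID2 lists held 4381 and 4393 peaks in HepG2 and 2264 and 3816 in THLE-2. The tags inside peaks were 45063 and 35364 for EZH2 and 45351 and 25664 for JARID2 in HepG2. In THLE-2 they were 88573 and 65622 for EZH2 and 13267 and 28034 for JARID2. The total depth of the libraries is unknown, and a gene without a listed peak is described as such, not as unbound.

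A few long RNAs took large shares of the tags, and which RNA led differed between the groups. NEAT1 (ENSG00000245532, chromosome 11, 65422774 to 65445540), the nuclear lncRNA that builds paraspeckles, took 40.2% of the tags in peaks of HepG2 JARID2 replicate 1 (Wilson interval 39.7 to 40.6) and 25.9% in replicate 2 (25.3 to 26.4). Its strongest peak spanned 65422799 to 65429610, was classed as intronic in the deposited list and held 11062 tags in replicate 1. MALAT1 (ENSG00000251562, chromosome 11, 65497688 to 65506516), the lncRNA of nuclear speckles encoded next to NEAT1, led the HepG2 EZH2 lists with 9.60% (9.33 to 9.88) and 7.78% (7.51 to 8.07) of the tags. MALAT1 also led the THLE-2 JARID2 lists with 11.7% (11.2 to 12.3) and 9.80% (9.46 to 10.2), and had no listed peak in either HepG2 JARID2 library. FN1, which encodes the matrix protein fibronectin, led the THLE-2 EZH2 lists with 6.45% (6.29 to 6.61) and 4.63% (4.47 to 4.79). Of 12 PRC2 subunits 10 had a peak in at least 1 library, and between 1 and 5 in each. RBBP7 had peaks in 6 libraries, with 4 tags in HepG2 EZH2 replicate 1, 5 in HepG2 JARID2 replicate 1, 11 and 14 in THLE-2 EZH2 and 3 and 3 in THLE-2 JARID2. EZH2 had 4 tags in HepG2 JARID2 replicate 2 and 3 in THLE-2 EZH2 replicate 1, and JARID2 had 4 tags in 1 library of each protein in THLE-2. SUZ12, another core subunit, had between 3 and 14 tags in 4 libraries and no peak in the other 4.

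Replicates resembled each other more than other pairs of libraries. Their mean Jaccard index of bound genes was 0.257 (4 pairs), the highest of the 105 ways to pair the libraries (exact p = 0.00952). Pairs that shared only the protein averaged 0.168, pairs that shared only the cell line 0.166 and pairs that shared neither 0.150 (8 pairs each). By the share of peaks with an overlapping partner the replicate pairs, at a mean of 0.255, again ranked first of 105 (exact p = 0.00952). The protein grouped the libraries by bound genes, with a Jaccard index higher by 0.0397 within than between proteins (1 of 35 divisions as large, exact share 0.0286). The cell line did not reach the threshold, with 0.0373 (2 of 35, share 0.0571). By overlapping peaks the order turned, at 0.0529 for the protein (2 of 35) and 0.0571 for the cell line (1 of 35). The protein grouping did not hold with lists of equal size, where the difference was 0.0626 and 2 of 35 divisions were as large, nor with the peaks above the median of each list (0.0503) or the overlap coefficient (0.0406), nor without either EZH2 replicate of HepG2 (0.0326 and 0.0358) or of THLE-2 (0.0183 and 0.0161). The cell line grouping passed with lists of equal size (0.0649), with the peaks above the median (0.0641), with the overlap coefficient (0.0460) and without HepG2 EZH2 replicate 1 (0.0431) or either THLE-2 EZH2 replicate (0.0306 and 0.0302). Stronger peaks recurred more. Of peaks with 10 or more tags, 60.8% (Wilson interval 58.3 to 63.2) in HepG2 EZH2, 46.6% (42.4 to 50.9) in HepG2 JARID2, 73.0% (71.6 to 74.4) in THLE-2 EZH2 and 60.9% (56.7 to 64.8) in THLE-2 JARID2 overlapped a peak of the other replicate. Of peaks with 3 or 4 tags, 9.93% (9.10 to 10.8), 16.0% (15.1 to 16.9), 15.0% (14.2 to 15.8) and 14.0% (12.98 to 15.0) did.

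A larger share of EZH2 peaks than of JARID2 peaks lay in coding exons, and a smaller share in introns. Coding exons held 42.0% ± 6.04 of EZH2 peaks and 16.7% ± 3.65 of JARID2 peaks (SD, n = 4 libraries each, two-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.04). Introns held 14.5% ± 4.96 of EZH2 peaks and 25.3% ± 2.46 of JARID2 peaks. The antisense strand of genes held 9.05% ± 4.41 and 23.9% ± 3.22, intergenic sequence 7.63% ± 3.46 and 15.9% ± 3.92, and noncoding exons 3.004% ± 1.38 and 5.65% ± 0.719. All 4 of these lower shares of EZH2 had an exact p = 0.0286 and an adjusted p = 0.04 (n = 4 each). With peaks weighted by length or with the peaks above the median of each list the directions were the same and the adjusted p of these 5 classes lay between 0.05 and 0.12, and without any 1 library it rose to at most 0.08. Among peaks with 10 or more tags, a setting chosen after seeing the data, coding exons differed by 22.9 percentage points (exact adjusted p = 0.1), and the antisense and intergenic classes by -2.99 and -4.20 (adjusted p = 0.28 and 0.467). The 3′ UTR held 21.2% ± 12.0 of EZH2 peaks and 9.49% ± 1.62 of JARID2 peaks, which did not pass (exact p = 0.114, adjusted p = 0.133, n = 4 each), and without HepG2 EZH2 replicate 2 its difference of 15.7 percentage points did. By cell line the share of EZH2 peaks in 3′ UTRs was 31.4% ± 3.28 in THLE-2 and 11.0% ± 2.59 in HepG2 (n = 2 each, not tested). The 5′ UTR held 2.59% ± 1.56 and 3.09% ± 0.381 (exact adjusted p = 0.486, n = 4 each). Between the cell lines no region class passed. The lowest p was that of the 5′ UTR, at 3.59% ± 0.494 in HepG2 and 2.09% ± 0.994 in THLE-2 (exact p = 0.0571, adjusted p = 0.4, n = 4 each).

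**Figure D1:**
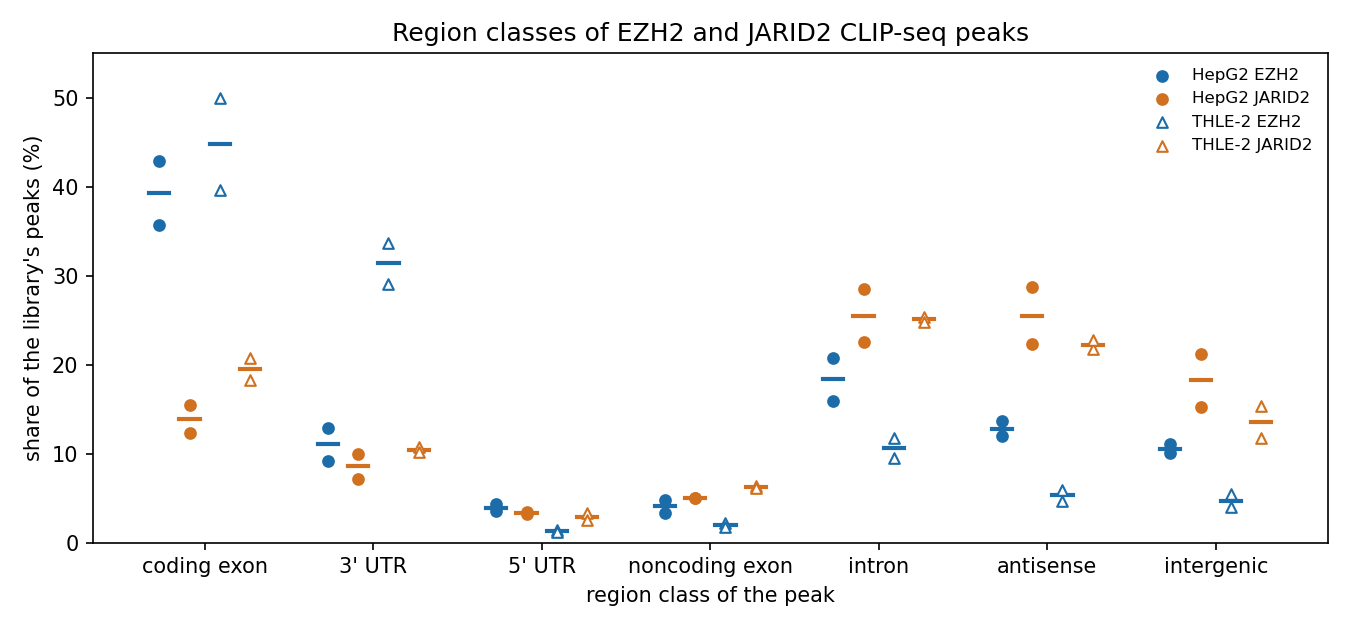
Percent of the peaks of each library in each of the 7 region classes, with 1 point per library and bars at the mean of the 2 replicates of a group. The EZH2 libraries all lie above the JARID2 libraries for coding exons, where the group means are 39.3% and 44.8% for EZH2 in HepG2 and THLE-2 against 13.9% and 19.5% for JARID2.

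EZH2 peaks were also longer and held more tags, without normalisation for the unknown total depth. Tags in peaks averaged 58655.5 per library for EZH2 and 28079 for JARID2 (n = 4 each), so an effect of depth stays open. The median peak length was 50.5 ± 13.7 bases for EZH2 and 25.8 ± 1.71 for JARID2 (SD, n = 4 each, exact p = 0.0286). Peaks with 10 or more tags made up 18.8% ± 2.86 and 7.48% ± 2.98 (exact p = 0.0286, n = 4 each). The mean of log2 tags per peak was 2.52 ± 0.10 and 2.08 ± 0.11 (exact p = 0.0286, n = 4 each), while the median of 4.5 and 3.5 tags did not pass (exact p = 0.171). The number of peaks did not pass either, with a log2 difference of 0.78 (exact p = 0.0857, n = 4 each) that rose to 0.98 and passed without HepG2 EZH2 replicate 2. Between the cell lines the exact p of these measures ranged from 0.486 to 0.829. Among bound genes 89.2% ± 3.92 were protein coding for EZH2 and 79.9% ± 0.894 for JARID2, and 7.37% ± 2.65 and 14.6% ± 1.03 were lncRNAs (exact p = 0.0286, adjusted p = 0.0667 for both, n = 4 each). Pseudogenes made up 1.65% ± 0.489 and 3.02% ± 0.395 (exact p = 0.0286, adjusted p = 0.0667, n = 4 each). Counted per peak instead of per gene, these 3 differences passed, at 11.1, -8.50 and -1.59 percentage points (exact adjusted p = 0.04, n = 4 each).

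The first comparison asked which RNAs of EZH2 differ between the carcinoma line and THLE-2. In HepG2 strong EZH2 peaks without a counterpart in THLE-2 lay on transcripts of CPS1, H19, CLU, ALPI and RMRP. CPS1 (ENSG00000021826, chromosome 2, 210477682 to 210679107), the entry enzyme of the urea cycle, had 1310 and 932 tags, with the strongest peak in a coding exon. The imprinted lncRNA H19 had 305 and 216 tags, CLU, a secreted chaperone, 194 and 300, and ALPI, an alkaline phosphatase, 62 and 41. RMRP, the RNA of the RNase MRP enzyme, had 231 and 378 tags. In THLE-2 those without an EZH2 peak in HepG2 lay on transcripts of THBS1, C3 and others. THBS1, a matrix glycoprotein, had 883 and 594 tags and C3, the central complement protein, 1101 and 678. AREG, a ligand of the EGF receptor, had 313 and 120, CD74, the invariant chain of class II antigen presentation, 272 and 196, and the chemokine CXCL5 138 and 122. ANPEP with 112 and 93, the stress cytokine GDF15 with 119 and 96, the matrix proteoglycan VCAN with 194 and 133 and the interferon-induced IFI6 with 63 and 41 belonged to the same class.

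In counts, 179 genes had EZH2 peaks in both HepG2 libraries and neither THLE-2 library, 999 genes the reverse, and 444 genes had peaks in all 4. Independent lists would share 175 genes, so the overlap was 2.54 times that (Fisher's exact p = 1.34e-108), and it made up 57.6% of the 771 HepG2 genes and 22.6% of the 1965 THLE-2 genes. Counted over genes bound in at least 1 replicate, the overlap was 0.911 times that of independent lists. Genes in all 4 libraries were led by MALAT1 with 4326 and 2753 tags in HepG2 and 542 and 422 in THLE-2, NEAT1, the snoRNA hosts GAS5 and SNHG1, RPL13, RPS12, CALR, NCL, RPL4 and ZFAS1. Over all libraries 100% of the tags of GAS5, SNHG1, RPS12, RPL4 and ZFAS1, 96.2% of those of RPL13 and 69.0% of those of NCL lay in peaks over snoRNAs. RefSeq snoRNAs were added after the result with GENCODE alone was seen, by which the share was 0% for GAS5, 74.1% for SNHG1 and unchanged for the others. None of the 22 gene lists differed between the exclusive classes by Fisher's exact test at an adjusted p under 0.05, and 1 did at an unadjusted p. That list was the mitochondrially encoded transcripts (Fisher's exact p = 0.0273, adjusted p = 0.600), with the transfer RNA genes MT-TP and MT-TA and MT-ND6 in HepG2 against MT-ND2 and MT-ATP6 in THLE-2. Of hepatocyte secreted proteins 0 fell in the HepG2 class and 4 in the THLE-2 class, namely C3, SERPINA1 with 98 and 95 tags, FGG with 9 and 5 and APOE with 9 and 4. Of cell cycle and replication genes 0 and 8 did, among them MCM7 with 26 and 17 tags and MCM4 with 14 and 32. Of ribosomal proteins 0 and 9 did, of TGF-beta pathway genes 0 and 4 (TGFB2 with 93 and 48 tags, SKIL with 16 and 4), and of splicing factors 0 and 4 (SF3B1 with 49 and 56). Mesenchymal genes numbered 1 (COL3A1, 22 and 29 tags) and 3 (THBS1 and COL5A2 among them), with 7 more in all 4 libraries. The Wnt pathway counted 1 (DVL1) and 3 (TNKS2, LGR4, DKK1), genes altered in hepatocellular carcinoma 0 and 3 (CDKN2A, RB1, CCND1), and the PI3K, AKT and mTOR pathway 0 and 3 (FOXO3, INSR, PDPK1). Lipid metabolism counted 0 and 2 (ACLY, ACSL1), histone genes 0 and 2, chromatin genes 1 (KMT2C) and 2 (CHD2, PBRM1), and epithelial genes 1 (JUP) and 1 (CLDN1). Short structured RNAs counted 2 (RMRP, RNU4-2) and 1 (RNU5A-1), snoRNA hosts 1 (SNHG17) and 0, partner lncRNAs 1 (H19) and 0, and markers of other cell types 0 and 1 (PTPRC, 3 and 28 tags). PRC2 subunits, PRC1 subunits, hepatocyte transcription factors and developmental transcription factors had no gene in either class. With lists of equal size the classes held 165 and 237 genes. A class is read from 2 libraries: without HepG2 EZH2 replicate 1 or 2 the HepG2 class held 755 or 838 genes, without THLE-2 EZH2 replicate 1 it held 272, and without THLE-2 EZH2 replicate 1 or 2 the THLE-2 class held 2271 or 2206.

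**Figure D2:**
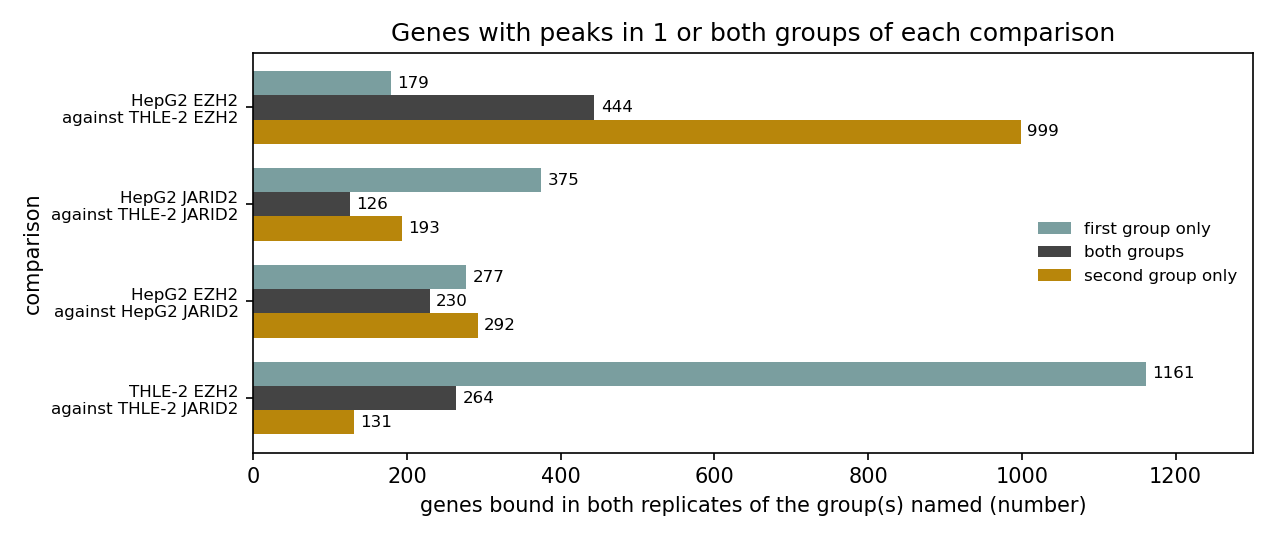
Number of genes in each of the 4 main comparisons that had peaks in both replicates of 1 side and neither of the other, or in both replicates of both sides. The largest bars are the 999 and 1161 genes of THLE-2 EZH2.

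The same question was put for JARID2. In HepG2 JARID2 had peaks on PVT1, the lncRNA next to MYC, with 17 and 27 tags, on H19 with 32 and 26 and on PDE3A, a cyclic nucleotide phosphodiesterase, with 54 and 13. EFCAB2 had 10 and 9 tags and the spliceosomal RNU5B-1 30 and 21. EIF4A2, a translation initiation helicase, had 87 and 46 tags, KANSL2 15 and 18 and NSD2, a histone H3 lysine 36 methyltransferase, 18 and 12. Over all libraries 100%, 95.4% and 60.0% of the tags of these 3 genes lay in peaks over snoRNAs. For NSD2 these were 30 of 50 tags, and the 50 include EZH2 tags, 6 and 4 in HepG2 and 4 and 6 in THLE-2. None of these EZH2 tags lay over a snoRNA. Without snoRNA peaks the chromatin genes shared by EZH2 in both cell lines, NSD2 among them, were still 4. The 30 tags are thus the JARID2 tags of NSD2 in HepG2, 18 and 12, all of them over snoRNAs. None of these genes had a JARID2 peak in THLE-2. In THLE-2 JARID2 had peaks on MALAT1 with 1558 and 2747 tags, THBS1 with 63 and 124 and CCN1, a matricellular protein, with 52 and 76. The metallothionein MT2A had 48 and 35 tags, the acute phase protein SAA1 15 and 35, CD74 31 and 29, CXCL5 23 and 25 and AREG 16 and 18. None of these had a JARID2 peak in HepG2.

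The classes held 375 genes for HepG2, 193 for THLE-2 and 126 in all 4 libraries, 3.37 times the 37.4 of independent lists (Fisher's exact p = 3.93e-37), and 0.997 times when genes bound in at least 1 replicate were counted. Genes in all 4 included NEAT1 with 18213 and 6639 tags in HepG2 and 732 and 1204 in THLE-2, SNHG1, RPL4, RPL13A, the mitochondrial ribosomal RNA MT-RNR2, RPL23A, RPL7A, NOP56 and RNU5A-1. Of the tags of SNHG1, RPL4, RPL13A, RPL23A, RPL7A and NOP56 100% lay in peaks over snoRNAs (74.1% for SNHG1 with GENCODE alone). No gene list passed by Fisher's exact test, and 1 had an unadjusted p under 0.05, the mitochondrial transcripts with 1 gene (MT-CO1) in HepG2 and 4 (MT-TA, MT-CO2, MT-ND2, MT-ATP8) in THLE-2 (p = 0.0478, adjusted p = 1). Mesenchymal genes counted 3 (COL5A1 with 34 and 39 tags, COL12A1, LOXL2) and 4 (CCN1, THBS1 and SPARC among them). Partner lncRNAs counted 3 (H19, PVT1, KCNQ1OT1) and 2 (MALAT1, MEG3), and PI3K, AKT and mTOR genes 3 (RICTOR and FOXO3 among them) and 0. The receptor gene MET with 18 and 8 tags was in the HepG2 class and RPS6KA3 in the THLE-2 class among genes altered in hepatocellular carcinoma. Hepatocyte secreted proteins and splicing factors had no gene in either class. With lists of equal size the classes held 184 and 179 genes. Without HepG2 JARID2 replicate 1 or 2 the HepG2 class held 1355 genes in either case, without HepG2 JARID2 replicate 1 the THLE-2 class held 312, and without THLE-2 JARID2 replicate 1 or 2 it held 1083 or 696.

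**Figure D3:**
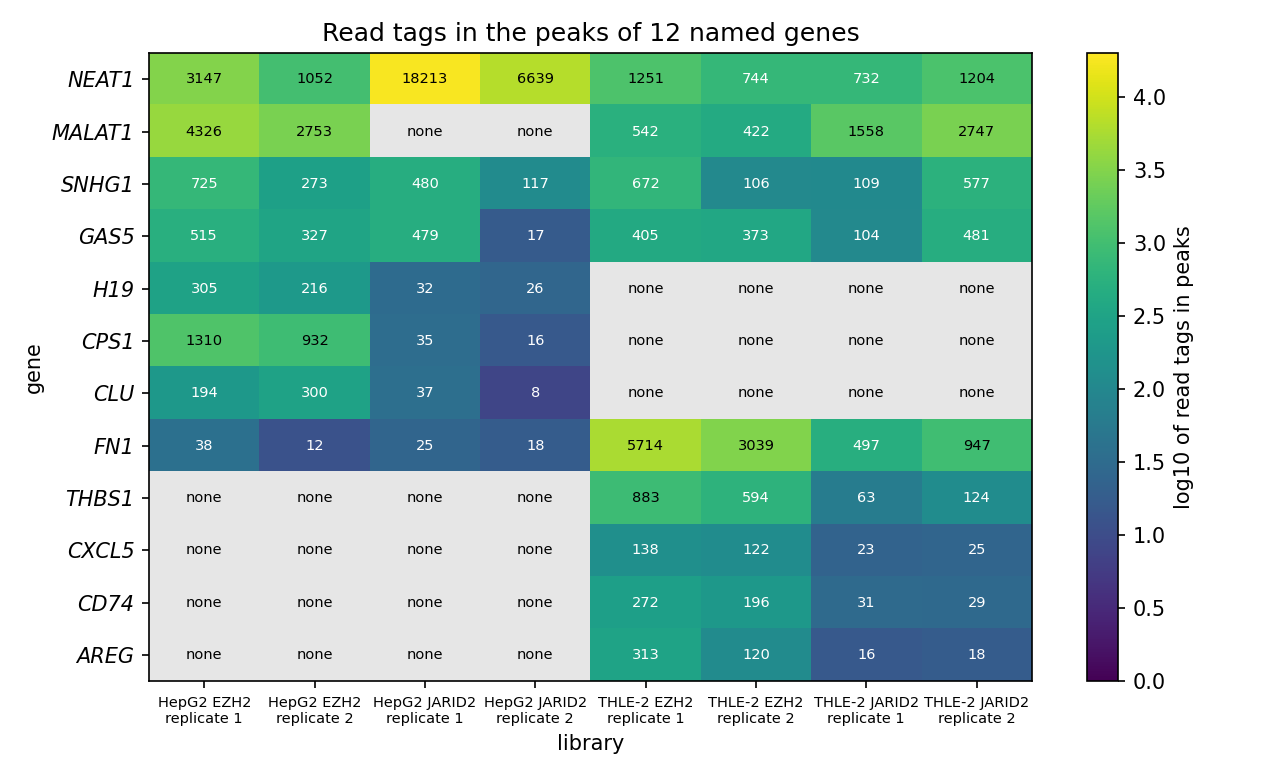
Tags in peaks of 12 named genes in each of the 8 libraries, as log10 of the tags, with "none" where no peak was listed. MALAT1 has no peak in the HepG2 JARID2 libraries, and CPS1, CLU and H19 have none in the THLE-2 libraries.

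The next comparison asked which RNAs EZH2 and JARID2, as subunits of 1 complex, share within HepG2. EZH2 alone had peaks on MALAT1, with 4326 and 2753 tags, on the minor spliceosomal RNA RNU12 with 62 and 50, and on PLEC, the cytoskeletal linker plectin, with 195 and 113. MIR663AHG with 417 and 94 tags, MT-TP with 86 and 122 and ALPI belonged to the same class, as did RPLP2 and RPS2, of whose tags 72.5% and 79.5% lay in peaks over snoRNAs. JARID2 alone had peaks on the spliceosomal RNAs RNU5A-1, with 43 and 32 tags, and RNU5B-1, with 30 and 21. MT-RNR2 with 74 and 42 tags, ANKRD24 with 20 and 18 and the lncRNA MIR31HG were in the same class. Spliceosomal RNAs do not part the proteins, since EZH2 had 15 and 22 tags on RNU4-2 in HepG2 and 28 and 25 on RNU5A-1 in THLE-2. Both proteins had peaks on NEAT1, RMRP (484 and 356 tags with JARID2), SNHG1, MT-CO3, RPL4, RNU5E-1, RPL7A, RPL13A and EIF4A2.

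The classes held 277 genes for EZH2 and 292 for JARID2, and 230 genes were shared, 3.83 times the 60.1 of independent lists (Fisher's exact p = 3.79e-84), and 1.03 times when genes bound in at least 1 replicate were counted. Of the gene lists 0 passed by Fisher's exact test and 0 had an unadjusted p under 0.05. The lowest p was that of chromatin remodellers and histone methyltransferases, with 4 genes (CHD3 with 34 and 14 tags, KMT2D, KMT2C, NSD1) for EZH2 and 0 for JARID2 (Fisher's exact p = 0.0555, adjusted p = 1). Lipid metabolism counted 3 (FASN, ACACA, CPT1A) and 0, and partner lncRNAs 1 (MALAT1) and 1 (KCNQ1OT1). With lists of equal size the classes held 139 and 153 genes. Without HepG2 EZH2 replicate 1 or 2 the EZH2 class held 993 or 1146 genes, without HepG2 JARID2 replicate 1 it held 470, and without HepG2 JARID2 replicate 1 or 2 the JARID2 class held 1223 or 1176.

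Of the 480 genes in THLE-2 with JARID2 peaks in both replicates 264, or 55%, had EZH2 peaks in both, which is 2.43 times the 109 of independent lists (Fisher's exact p = 1.10e-56), and 0.903 times when genes bound in at least 1 replicate were counted. These included MALAT1, NEAT1, SNHG1, RPS12, RPL4, FN1, B2M, GAS5 and ATP5F1B, of which the last had 100% of its tags in peaks over snoRNAs (50.4% with GENCODE alone). FN1 (ENSG00000115414, chromosome 2, 215360440 to 215436172) had 5714 and 3039 tags with EZH2 and 497 and 947 with JARID2. EZH2 alone had peaks on 1161 genes, among them the calcium pump ATP2A2 with 212 and 131 tags, B4GALT1 with 248 and 121, the protease HTRA1 with 154 and 104, the complement protease C1S with 104 and 62 and CD81 with 77 and 63. JARID2 alone had peaks on 131 genes, among them MT-RNR2 with 32 and 558 tags, MT-ND6 with 20 and 179, the collagenase MMP1 with 27 and 13, and the snoRNA host SNHG17.

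Mitochondrial transcripts were the 1 list of 22 that passed, with 2 genes (MT-CO1 with 111 and 235 tags, MT-ATP6) in the EZH2 class and 5 (MT-RNR2, MT-ND6, MT-TA, MT-CO2, MT-ATP8) in the JARID2 class (Fisher's exact p = 0.000177, adjusted p = 0.0039). It did not pass with lists of equal size (Fisher's exact adjusted p = 0.509) nor without THLE-2 JARID2 replicate 1 (adjusted p = 0.457), and no other list had an unadjusted p under 0.05. Ribosomal proteins counted 24 and 0 in the 2 classes (Fisher's exact p = 0.162, adjusted p = 0.847), cell cycle genes 8 and 0 (TOP2A with 57 and 55 tags, CENPF with 27 and 72), and chromatin genes 8 and 0 (KMT2A with 15 and 28, SETD2 with 15 and 14). Genes altered in hepatocellular carcinoma counted 6 and 0 (IL6ST with 167 and 76 tags, MET with 103 and 76), splicing factors 5 and 0 (HNRNPM with 52 and 109, HNRNPK with 81 and 49), and mesenchymal genes 4 and 0 (CDH2 with 144 and 66). The PRC1 subunit CBX2, with 6 and 5 tags, and MEG3, with 6 and 9, were in the JARID2 class. With lists of equal size the classes held 222 and 171 genes. Without THLE-2 EZH2 replicate 1 or 2 the EZH2 class held 2515 or 2407 genes, and without THLE-2 JARID2 replicate 1 or 2 the JARID2 class held 800 or 524.

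Genes shared by both sides of a comparison gathered in a few lists, by a test chosen after seeing the data. Its background is all genes bound in at least 1 library, and transcript length and RNA level were not taken into account. The 4 comparisons share libraries, so a list that passes in several has not passed independent tests. Mesenchymal and matrix genes stood out in all 4 comparisons: 7 of the 22 that were bound in any library were shared by EZH2 in both cell lines, 3 by JARID2 in both cell lines, 6 by both proteins in HepG2 and 10 by both proteins in THLE-2 (Fisher's exact adjusted p = 0.00056, 0.0166, 0.000113 and 5.91e-09). FN1, TGFBI, LOXL2, COL4A2 and COL5A1 were among them. The snoRNA host genes counted 11, 9, 12 and 7 of 18 (exact adjusted p = 1.41e-09, 2.06e-11, 3.21e-14 and 3.90e-06). Ribosomal proteins counted 22, 6, 10 and 13 of 69 (exact adjusted p = 3.28e-11, 0.00363, 0.000113 and 1.32e-06), and partner lncRNAs 4, 3, 5 and 4 of 14 (exact adjusted p = 0.0247, 0.00532, 0.000113 and 0.00362). Mitochondrial transcripts passed for JARID2 in both cell lines with 4 of 26 (MT-RNR2, MT-ND5, MT-ND4, MT-CYB, exact adjusted p = 0.00363) and for both proteins in HepG2 with 5 (adjusted p = 0.0023). Without peaks over snoRNAs the snoRNA hosts counted 2, 0, 1 and 0 and the ribosomal proteins 5, 0, 2 and 0, none of which passed. Partner lncRNAs then counted 2, 1, 3 and 2, and passed only for both proteins in HepG2 (Fisher's exact adjusted p = 0.321, 0.591, 0.0111 and 0.329).

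Across both proteins, 60 genes separated the cell lines, 28 with peaks in all 4 HepG2 libraries and no THLE-2 library and 32 the reverse. The 28 included CPS1, H19, CLU, PDE3A, the neural adhesion molecule L1CAM and F9, which encodes coagulation factor IX. The 32 included THBS1, CD74, AREG, the chemokines CXCL5, CXCL6 and CCL20, the Wnt inhibitor DKK1, TGFB2 and the DNA methyltransferase DNMT3A. The proteins were separated by 76 genes, 72 with peaks in all EZH2 libraries and no JARID2 library, among them the glycolytic enzyme ENO1, ATP2A2, the phosphatase DUSP1, PLXNB2, CDH2, CHD3 and NSD1. The 4 in the other direction included MT-RNR2, LINC00506 and LINC01572. The examples named here were chosen after their values were seen. Of the 35 ways to divide the libraries into 4 and 4, 1 gave as many genes as the protein (exact share 0.0286), and 2 gave as many as the cell line (0.0571), where the other was the division by protein. Divisions along neither gave at most 38 genes, but most of these part replicates, which resembled each other more than other pairs. Without any 1 of the 4 JARID2 libraries 3 of 35 divisions were as large as the protein. With lists of equal size the counts were 52 for the cell line and 32 for the protein, with exact shares of 0.0286 and 0.0571. Without THLE-2 JARID2 replicate 1 or 2 the cell line count was 179 or 126, without HepG2 EZH2 replicate 1 or 2 it was 99 or 96, and without HepG2 JARID2 replicate 2 it was 91. Without HepG2 EZH2 replicate 1 or 2 the protein count was 160 or 190, without HepG2 JARID2 replicate 1 it was 118, and without THLE-2 JARID2 replicate 2 it was 119.

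The exonic peaks of 6 of the 8 libraries held more G than flanks of the same transcripts. The mean difference was 2.55 ± 2.51 percentage points (SD, n = 8, exact sign-flip p = 0.0313, adjusted p = 0.0938 over 3 measures), which did not pass. The 2 libraries below 0 were those of EZH2 in THLE-2, at -1.59 and -0.88, where peaks held 38.9% and 40.8% GC and flanks 45.4% and 45.8%. The mean difference in G was 4.34 in HepG2 and 0.767 in THLE-2 (two-sided exact permutation p = 0.0286, the smallest possible, not adjusted, n = 4 each). The THLE-2 mean joins these 2 negative values with 2.95 and 2.60 for JARID2. By protein the mean was 1.73 for EZH2 and 3.38 for JARID2 (two-sided exact permutation p = 0.371, n = 4 each). The GC percent differed by 0.586 points (exact p = 0.703, n = 8) and the percent of peaks with a run of 3 or more G by 4.47 (exact p = 0.133, n = 8).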

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

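No test was run on the differences in this part, which stand here because the libraries of 1 group all moved one way and those of the other group the opposite way, with 2 libraries on each side of each contrast. The number of peaks was lower in HepG2 than in THLE-2 for EZH2 (log2 difference -0.97) and higher for JARID2 (0.58), so that the 2 contrasts differed by -1.54. The number of bound genes did the same, with log2 differences of -0.89 for EZH2 and 0.42 for JARID2, which lie -1.31 apart. The share of peaks in 5′ UTRs was higher for EZH2 than for JARID2 in HepG2 by 0.617 percentage points and lower in THLE-2, at -1.63 points, a distance of 2.25. The share of peaks in noncoding exons was 2.14 points higher in HepG2 than in THLE-2 for EZH2 and -1.23 points different for JARID2, a distance of 3.37. The share of bound genes in the remaining RNA biotypes was 0.524 points higher in HepG2 for EZH2 and -0.206 points different for JARID2, a distance of 0.730.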

How the results depend on the processing

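The antisense, snoRNA, mitochondrial, 10-tag and recurring-peak settings and the test of genes bound on both sides were chosen after seeing the data; all others were planned. Of the results that answer a comparison, 477 kept their direction and their side of the threshold, or for counts stayed within 1.5 times, under single alternatives (17 of these values are fixed by construction under the replicate block), 72 moved further, 62 lost and 16 gained the threshold and 14 reversed. Where no reason is given, the cause was not tested. What limits all of these counts is the unknown total depth, since a gene with fewer than 3 tags has no listed peak. Sequence of intronic peaks was not run for want of a genome sequence. The exclusive classes named 62 distinct genes, which were chosen for strong peaks and so cannot show stability when weak peaks are removed. Of these genes 33 changed class with at least 2 peaks per gene, 12 with assignment by midpoint, 6 with antisense peaks counted, 10 without snoRNA peaks and, by construction, the 6 mitochondrial ones without mitochondrial peaks.

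Exclusive classes shrink by construction when peaks are removed. In the order EZH2 between cell lines, JARID2 between cell lines, HepG2 between proteins and THLE-2 between proteins, the peaks above the median of each list gave 118 and 535, 192 and 116, 136 and 150, and 563 and 70 genes. At least 2 peaks per gene gave 51 and 496, 41 and 37, 127 and 21, and 615 and 12. Lists of equal size gave 237 for THLE-2 with EZH2, 184 for HepG2 with JARID2, 139 and 153 in HepG2 and 222 for EZH2 in THLE-2. With antisense peaks counted the JARID2 classes held 578 in HepG2 against THLE-2, 477 in HepG2 against EZH2 and 209 in THLE-2 against EZH2. With genes bound in at least 1 replicate the classes held 1414 and 3478, 2335 and 1586, 1862 and 2107, and 3761 and 1193, and the overlap fell to 0.911, 0.997, 1.03 and 0.903 times chance. The background consists of genes bound in at least 1 library, so unions fill most of it. With 1 replicate left out, the classes ranged from 234 to 838 and 1214 to 2271, from 423 to 1355 and 235 to 1083, from 348 to 1146 and 358 to 1223, and from 1315 to 2515 and 159 to 800, since 1 library then decides a side.

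Genes separating the cell lines numbered 16 with at least 2 peaks per gene and 79 to 179 with 1 replicate left out. Genes separating the proteins numbered 36 with above-median peaks and 32 with lists of equal size (2 of 35 divisions as large in both), and 98 to 190 with 1 replicate left out. The grouping by cell line passed with above-median peaks (0.0641), equal size (0.0649) and the overlap coefficient (0.0460), and the grouping by protein no longer did (0.0503, 0.0626 and 0.0406). With 1 replicate left out the 2 values ranged from 0.0302 to 0.0431 and from 0.0161 to 0.0576. Covered length instead of peak number differed between the proteins by 1.59 on the log2 scale and passed, as did the mean of log2 tags by 0.44 instead of the median. With 1 replicate left out the log2 difference in peak number ranged from 0.56 to 0.98 between the proteins and from -0.58 to 0.0913 between the cell lines.

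Region differences between EZH2 and JARID2, in percentage points for coding exon, noncoding exon, intron, antisense and intergenic, were 26.6, -5.84, -15.0, -11.4 and -7.75 weighted by length and 29.5, -3.04, -14.0, -14.0 and -9.94 with above-median peaks. With 10 or more tags they were 22.9, -7.39, -23.9, -2.99 and -4.20, all short of the threshold. The adjusted p depends on how many classes reach the smallest p, so that 1 class less ends the calls. Among peaks found in both replicates the 5′ UTR passed at -1.95 and the noncoding exon did not at -3.45. With 1 replicate left out the 5 differences ranged from 22.7 to 27.4, -3.25 to -2.21, -12.9 to -9.14, -16.3 to -13.2 and -9.64 to -6.49, with adjusted p up to 0.08, and the 3′ UTR ranged from 7.56 to 15.7. Between the cell lines the coding exon ranged from -11.0 to 0.3301 and the noncoding exon from -0.346 to 1.22. Counted per peak, protein coding (11.1), lncRNA (-8.50), snRNA (-0.155), pseudogene (-1.59) and genes absent from the annotation (-0.376) passed. The snoRNA class was 0.0578 with above-median peaks and ranged from -0.0852 to 0.0413 with 1 replicate left out. The GC difference of peaks ranged from -0.00871 to 1.61 with 1 replicate left out.

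Gene lists past the threshold ranged with 1 replicate left out from 0 to 3 and 0 to 2 between cell lines and from 0 to 1 and 1 to 2 between proteins. In THLE-2 the count was 0 with lists of equal size and 0 by the share of bound genes per library. The mitochondrial list there had a class difference of 3 genes, 5 with equal size (exact adjusted p = 0.509) and 2 to 5 with 1 replicate left out (adjusted p from 3.91e-07 to 0.457). Without snoRNA peaks 0 snoRNA hosts and 0 ribosomal proteins were shared by JARID2 in both cell lines, and 0 and 0 by both proteins in THLE-2. Partner lncRNAs then passed only for both proteins in HepG2.

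A replicate block, which pairs libraries by replicate number, leaves the classes and the differences as they are by definition, and only the p can change. For the 60 genes separating the cell lines the smallest possible p of 0.125 was reached, for the difference of -0.19 in peak number exact p = 0.875, and adjusted p for regions ranged from 0.175 to 0.75 (exact flips). The numbers pair nothing that could be measured, with correlations of replicate deviations across genes from -0.0489 to 0.0312.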

Other observations

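In all 8 libraries 71 genes had a peak, led by NEAT1 and SNHG1. Away from snoRNAs they included ITGB1, the integrin beta 1 chain, with 132 and 103 tags for EZH2 in HepG2, 126 and 10 for JARID2 in HepG2, 1005 and 646 for EZH2 in THLE-2 and 73 and 112 for JARID2 in THLE-2, of which 6.89% lay in peaks over a snoRNA (0% with GENCODE alone). PSAP, the precursor of lysosomal saposins, had 245 and 323 tags for EZH2 in HepG2, and B2M, the light chain of class I antigen presentation, 298 and 226 for EZH2 in THLE-2. PRKDC, the catalytic subunit of the DNA-dependent protein kinase, had 479 and 124 tags for EZH2 in HepG2 and 44 and 9 for JARID2. The metalloproteinase inhibitor TIMP2 and the matrix proteins EFEMP1, FBLN1, FBN1 and TGFBI were among the 71 as well. These genes were picked after their values were seen.

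The tests of weak peaks, recurring peaks, snoRNA peaks, housekeeping genes and exchanged labels and the counts of other divisions were chosen after the results were seen, though for weak and recurring peaks the limits were set before these subsets were examined.

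EZH2 peaks lay in coding exons 25.3 percentage points more than JARID2 peaks. Among peaks of 10 or more tags, of which a library held 139 to 2074, 90.5% of the difference was left (44.6% ± 7.57 against 21.7% ± 10.9 after 42.0% ± 6.04 against 16.7% ± 3.65 over all peaks, SD, n = 4 each, exact p = 0.0286). The adjusted p rose from 0.04 to 0.1 and no longer passed, as fewer of the 7 classes reached the smallest exact p. Peaks over snoRNAs were not removed for this. A JARID2 library held 97 to 210 of them at any strength, beside 139 to 391 peaks of 10 or more tags. In the EZH2 libraries they numbered 144 to 201, beside 708 to 2074. How many were strong was not counted. They may lower the coding share of strong JARID2 peaks, so this setting does not exclude weak peaks filling the JARID2 lists. In the same setting the antisense difference went from -14.8 to -2.99 percentage points and the intergenic one from -8.27 to -4.20, so for these weak peaks stay open too. Peaks that do not recur do not account for the coding exon difference, with 95.4% left among peaks found in both replicates (39.98% ± 4.38 against 15.8% ± 5.17, exact p = 0.0286, n = 4 each). The 2 antibodies, total depth and the treatment of duplicate reads differ or may differ with the protein and were not tested. A preference of EZH2 for spliced mRNA thus stays a hypothesis.

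Genes with peaks on both sides of a comparison were enriched in snoRNA hosts. The snoRNA itself, credited to its host gene by the annotation, may be the source: 95.2% of the tags of the 10 host genes tested lay in peaks over an annotated snoRNA or small Cajal body RNA (60.5% with GENCODE alone, before RefSeq was added). Peaks over such RNAs held from 4.51% to 19.8% of the tags of a library. Binding of host transcripts outside these peaks was seen for NCL and RACK1, where 69.0% and 69.5% of the tags lay in them. Whether snoRNAs bind EZH2 and JARID2 or are shared background is open, because IgG values were not used here.

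Of the 25 genes in the list of hepatocyte secreted proteins 2 had a listed peak in HepG2 (ITIH1 with 4 tags and C3 with 3), and ALB, AFP, APOA1, APOB and FGB had none. Outside that list, CLU and F9, which also encode secreted proteins, had peaks in all 4 HepG2 libraries. Removal of abundant mRNAs as a class by the comparison with IgG is argued against by 10 of 20 housekeeping genes with peaks in both HepG2 EZH2 libraries, among them ACTB with 10 and 22 tags and P4HB with 91 and 155. The 10 include EEF2 and TPT1, of whose tags over all libraries 46.7% and 60.6% lay in peaks over snoRNAs. The other 10 lacked a peak in at least 1 of the 2 libraries. Removal of part of the abundant transcripts stays open, since abundance was not measured here. An exchange of the cell line labels cannot be told apart from correct labels by this list, because ALB, AFP, APOA1, APOB and FGB had no peak under either label, and 5 of the 25 genes had one in THLE-2 (C3 with 1101 and 678 tags and SERPINA1 with 98 and 95 for EZH2) against 2 in HepG2. Outside the list CPS1 and H19 had peaks in all 4 HepG2 libraries and in no THLE-2 library, which goes the way of the labels. These 2 genes were picked after their values were seen, from 28 genes with that distribution, so they do not decide the question. A biological difference between the cell lines was not tested, since RNA levels were not used here.

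In the lists as deposited 1 of 35 divisions was as large as the 76 genes separating the proteins, the fewest possible. The highest of the others held 60 genes. This count cannot exclude chance, because no lower share is possible and replicates resembled each other more than other pairs did. Of 100 simulated runs without planted genes 3 had a share under the threshold. These runs drew each library independently, so they do not show how often replicates nested in groups would reach it. The first rank depends on the lists: those of EZH2 were longer on average, and 72 of the 76 genes lay on their side. It did not hold with lists of equal size or above-median peaks, where 2 of 35 divisions were as large as its 32 and 36 genes, nor without any 1 of the 4 JARID2 libraries, where 3 of 35 were. For the 60 genes separating the cell lines the count of 2 of 35 as large does not exclude chance in the lists as deposited. The 1 other is the division by protein, with 76 genes. Divisions along neither axis gave at most 38. Most of them part replicates, which resembled each other more than other pairs, so this gap cannot exclude chance either. For the cell lines 1 of 35 divisions was as large as the 52 and 59 genes with lists of equal size or above-median peaks.

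That the G content of exonic peaks only mirrors the GC content of the transcripts cannot be told apart from a preference for G, since the difference to flanks of the same transcripts was 2.55 percentage points on average, above 0 in 6 libraries and below 0 in 2.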
